A study of Homo sapiens with 24 samples.

How the data were processed

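Human T cells were purified by enrichment columns from the blood of 3 healthy donors, per the labels, and gene expression was measured on 12 two-colour Agilent whole-genome oligonucleotide arrays. On each array, RNA from cells exposed to a chemokine was labelled with the green dye Cy3, and RNA from untreated cells of the same donor was labelled with the red dye Cy5. The 24 deposited samples are the 2 dye channels of these 12 arrays, and the 2 files deposited for each array were identical for 12 of 12 arrays. The labels describe cells kept in six-well plates with 100 ng/ml of chemokine for 3 h, total RNA isolated with Trizol, and complementary RNA amplified linearly from small amounts before labelling. The dyes were never swapped between treated and untreated cells. An effect of the dye on a single probe therefore remains in every comparison against untreated cells. When treated groups are compared with each other, it cancels only as far as it is equally large on their arrays.

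Groups were taken from the sample titles: CXCL12 and CCL19 for cells treated in plates, and CXCL12_migrated and CCL19_migrated for cells that had migrated, each with 3 arrays from the same 3 donors. Some labels contradict these titles. The source names of the migrated samples of donors 2 and 3 name other chemokines, the treatment text of the CCL19 and migrated samples names CXCL12, and the series text gives an overnight exposure where the sample text gives 3 h. The labels do not state whether the untreated aliquots of one donor are the same RNA, nor how the migrated cells were collected.

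Per the file headers, the scanner software (Agilent Feature Extraction A.7.5.1, per the labels) gave for each spot the mean intensity of its pixels in each channel and the median intensity of the local background. It also gave processed intensities after background subtraction by spatial detrending and dye normalization, and a log10 ratio of red to green, per the file headers. The deposited table of values holds a score for each sample and channel, made by the authors, which was checked to be an exact straight line of the log10 processed intensity of that channel, with slopes from 1.37 to 1.78 and medians from −0.046 to 0.031. It covers 32142 of the 41675 features that are not control spots, and the filter behind this is not stated. The median Cy3 intensity per array was 513.1 to 610.5 and the median Cy5 intensity 452.9 to 641.3. Between 84.2% and 94.4% of features in Cy3, and between 83.3% and 94.6% in Cy5, were well above background. The number of arrays, 3 per group, limits the precision.

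Spot intensities were read from the deposited array files and analysed with limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8) and statmod 1.5.0; Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for annotation and drawing. Background was corrected with the normexp method and an offset of 50, and each array's log2 ratio of Cy3 over Cy5 was adjusted for intensity by a loess curve. Spots that the software marked as non-uniform or as outliers among replicate spots were left out, and spots of one probe were averaged. Probe names came from the RefSeq accessions in the files for 20057 features, from a symbol or synonym for 478 and from the description for 1, which is the WNT5A probe A_23_P211926. The brightest probe stood for each of the 15563 symbols. A gene was kept when its probe was well above background in either channel on at least 3 of the 12 arrays, which left 15333 genes. The probes of the other genes fixed in advance were A_23_P131676 for ACKR3, A_23_P343398 for CCR7, A_23_P397999 for FZD5 and A_23_P102000 for CXCR4. Genes on chromosome Y and XIST were left out.

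A single limma fit with 1 mean per group over the 12 arrays gave 10 comparisons, 4 of a group's mean log2 ratio against 0 (versus untreated) and 6 between groups, each tested in both directions with limma's moderated test and Benjamini-Hochberg adjustment over genes at 0.05. The p-values measure the spread between the arrays of these 3 donors. Gene lists were tested with camera (preset correlation between genes 0.01, two-sided), adjusted over the 28 lists of each comparison, which makes 280 list tests. Beside it were run camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance without comparing them with other genes. The lists were the genes of noncanonical Wnt signalling; Wnt ligands, receptors and inhibitors; the beta-catenin pathway; chemokine receptors; chemokines; T cell homing; motility and actin; immediate-early genes; T cell activation; NF-kB targets; interferon-stimulated genes; heat shock; hypoxia and glycolysis; cell cycle; apoptosis and p53; naive T cells; memory and effector T cells; the T cell receptor complex; regulatory T cells; ribosomal proteins; the mitochondrial respiratory chain; and markers of monocytes, B cells, NK cells, platelets, erythroid cells, neutrophils and dendritic cells. Several lists share genes.

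The groups, comparisons, tests, lists and alternatives, unless stated otherwise, were chosen before the data were examined. Named genes follow a rule of that kind. In a comparison with passing genes, they are the 8 with the largest positive and the 8 with the largest negative log2 change among passing genes that had a value on every array compared, the same sign on every array (or no overlap between groups), and a mean log2 intensity above the median of 7.66. Up to 4 members with the smallest p of each list described, and WNT5A, CXCR4, ACKR3, CCR7 and FZD5 whatever their values, are named as well. Where no gene passed, the 3 genes with the smallest p in each direction are named as not passing, without a value where the probe was not well above background on every array.

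The replicate number marks the donor, since the labels give the same donor for equal numbers. As a check of that pairing, deviations of the arrays from their group means correlated across genes with a median r of 0.481 (lowest 0.174) between arrays of one donor (15 pairs), without 1 array that stood apart. The log ratios themselves correlated with a median r of 0.74 within donors and 0.577 between donors (40 pairs). Genes are not independent replicates. The extraction day, per the file headers, is the day on which the Feature Extraction software processed an array, and not a day of RNA isolation. The headers place donor 1 on one extraction day and donors 2 and 3 on another, each day with all 4 groups. Leaving out replicate 1 thus gives the result within the later day. The first day held 1 array per group and gave no test of its own.

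Alternatives were the Agilent processed signals, median centring in place of loess, quantile scaling, no background subtraction, no filter or a filter of 6 arrays on dim probes, all probes as separate features, the donor as a fixed block (replicate block) or a random block, only the arrays compared, extraction day as a block, the deposited value table, the Cy3 channel alone, and leaving out each array or donor. CXCL12 replicate 3 stood apart from the other arrays, so settings without it, for all comparisons and with the replicate block, were added after the data were seen. The fit was tested on simulated data with the spread of these arrays: of genes given a log2 change of 1, 74.6% were recovered in a comparison of CCL19_migrated with untreated cells, 68.7% between CXCL12 and CCL19 and 79.1% between migrated and plate-treated cells. Of genes given 0.5, 34.3%, 23.9% and 43.3% were recovered. The simulated noise was independent between arrays and genes, with the same spread on every array. It held no donor effect and no array that stood apart, so these shares may not hold for the real arrays.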

Results

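Gene expression was measured in T cells of 3 healthy donors after exposure to CXCL12, a chemokine that binds CXCR4 and ACKR3, or to CCL19, a chemokine that binds CCR7. For each chemokine there were cells treated in plates and cells that had migrated, which makes 4 groups of 3 arrays, and every array paired the treated cells with untreated cells of the same donor. Values are log2 ratios of treated over untreated, with the standard error of the fit from 3 arrays per group, and genes are given by symbol. One array, CXCL12 replicate 3, stood apart from the others: its Cy3 intensities correlated across genes with those of the other arrays at 0.601 to 0.741, against 0.914 to 0.99 among the others, while its Cy5 intensities correlated at 0.932 to 0.987. Its log2 ratios had an SD of 0.855, against 0.226 to 0.539 on the other arrays, so values without it are given wherever it changed a result. The series title names WNT5A, a ligand of the Wnt family that acts largely without beta-catenin.

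The CXCL12 arrays against untreated cells ask what CXCL12 alone changed in plates. The genes nearest to passing were TNFSF14 and TNFRSF4, a ligand and a co-stimulatory receptor of the tumour necrosis factor family made by activated T cells, and CD2BP2, which binds the tail of the adhesion receptor CD2. TNFRSF4 was higher by 0.70 ± 0.10, or 1.62-fold, on 3 of 3 arrays, with an adjusted p of 0.108. TNFSF14 (0.57 ± 0.08) and CD2BP2 (0.61 ± 0.08) had the same adjusted p, also on 3 of 3 arrays. Lower on 3 of 3 arrays, at an adjusted p of 0.11, were KLF8, a transcription factor (−0.54 ± 0.08), GIPR, a hormone receptor (−0.46 ± 0.07; other probe −0.04), and PGM2L1, a sugar-phosphate enzyme whose probe was well above background in Cy3 on 2 of 3 arrays. In limma, 0 of 15326 genes passed, with 3206 at an unadjusted p under 0.05. The count was 982 (611 higher, 371 lower) with the donor as a fixed block, a count that speaks of these 3 donors only, 1256 (846 higher, 410 lower) with quantile scaling, 200 with extraction day as a block, 28 with the Agilent processed signals, 1 without CXCL12 replicate 2 and 0 within the later extraction day. No gene passed with the donor as a random block, with median centring, without background subtraction or with only the arrays compared. All of the genes named above passed with the fixed donor block, TNFRSF4 at an adjusted p of 0.0167. With CXCL12 replicate 3 left out, 0 genes passed and 1874 had an unadjusted p under 0.05, and 3142 passed with the donor block as well.

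The receptors of these chemokines showed how far a single array moved the CXCL12 means. CXCR4 averaged −1.76 ± 0.77 on the CXCL12 arrays with an adjusted p of 0.232, lower on 2 of 3 arrays, and 0.00 without CXCL12 replicate 3. CCR7 averaged −1.38 ± 0.55 (adjusted p 0.206, lower on 2 of 3 arrays) and −0.15 without that array. Because the spread is shared, these errors of CXCR4 and CCR7 hold in every group, and that array limits their tests there too. ACKR3 was −0.10 ± 0.09 (0.496). Camera placed 5 lists lower in CXCL12-treated cells: ribosomal proteins (adjusted p 1.57e-05, list median −1.39), the mitochondrial respiratory chain (0.000942, −0.60), naive T cell genes (0.00616, −0.54), T cell homing (0.0154, −0.45) and memory and effector T cell genes (0.0499, −0.25, and 0.0727 with the donor block). No list passed with an estimated correlation, where each of the 5 had an adjusted p of 0.967. Without CXCL12 replicate 3, adjusted p-values were 0.318 for the respiratory chain, 0.318 for naive T cell genes, 0.842 for homing and 0.149 for memory genes, and ribosomal proteins were higher, with a median of 0.25 and an adjusted p of 0.0158. Without it camera also placed motility and actin genes (0.000558, median 0.22), immediate-early genes (0.00488, 0.18), interferon-stimulated genes (0.00488, 0.14), hypoxia and glycolysis (0.0112, 0.14) and NF-kB targets (0.0187, 0.19) higher, while with the donor block and an estimated correlation no list passed without that array (0.698 to 0.993).

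The CCL19 arrays against untreated cells ask the same of CCL19. Among the increases, PSMC3 and PSMD11, subunits of the cap of the proteasome, were higher by 0.92 ± 0.16 (1.89-fold, adjusted p 0.0304) and 0.91 ± 0.20 (0.0405), on 3 of 3 arrays each. SYMPK, a scaffold of messenger 3' end processing, was higher by 1.32 ± 0.32 (2.49-fold, 0.048). NRBP1, a pseudokinase of vesicle transport, was higher by 0.86 ± 0.13 (0.03) on 3 of 3 arrays. TNFRSF12A, receptor of the cytokine TWEAK, the homeobox gene HOXB2 and the sulfurtransferase gene MPST rose by 0.72 to 0.81 on 3 of 3 arrays; a dimmer probe of HOXB2 read 0.17. Decreases were smaller. They included the cilium gene RPGR (−0.54 ± 0.13, adjusted p 0.048), the secreted ribonuclease RNASE6 (−0.48 ± 0.09, 0.0304), GIPR (−0.47 ± 0.07, 0.03; other probe −0.06) and the Wnt ligand WNT4 (−0.42 ± 0.10, 0.0432; other probe 0.15), all on 3 of 3 arrays. The protease inhibitor A2ML1, the ceramide synthase gene CERS6, the mitochondrial enzyme gene DHTKD1 and the keratin-associated KRTAP9-4 fell by 0.41 to 0.43 log2 units. Of the 28 genes named in this text that passed with CCL19, 4 kept the call with the processed signals (PSMC3 and NRBP1 among them), 0 with the deposited value table, 12 with the stricter filter and 0 without any one of CCL19 replicate 1, 2 or 3. Median centring ended the calls of PSMD11 (adjusted p 0.123) and KRTAP9-4 (0.0507).

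In all, 715 of 15325 genes passed in the CCL19 comparison, 449 higher and 266 lower, which is 62.8% higher. That share was 76.6% with the processed signals (167 genes), 76.9% with the deposited value table (26) and 50% without background subtraction (1810). No gene passed without any one of the 3 CCL19 arrays, and none within the later extraction day; 1175 passed without CXCL12 replicate 3 and 2261 with the donor as a fixed block, for these 3 donors only. Passing genes lay mostly among dim probes, 422 among the dimmest 20% of genes and 3 among the brightest 20%. Each gene's spread is estimated over all 12 arrays. On CXCL12 replicate 3 the brightest 20% of genes had a median log2 ratio of −0.844 and the dimmest 20% 0.136, so that array can widen the spread of bright genes. How far this set the share of dim genes was not tested. CXCR4 (0.13 ± 0.77, adjusted p 0.947), CCR7 (0.03 ± 0.55, 0.984) and ACKR3 (0.07 ± 0.09, 0.704) did not pass. No list passed with camera (adjusted p 0.425 to 0.899), with an estimated correlation (0.939) or with fry (0.673 to 0.91). In the hypoxia and glycolysis list ALDOC and PFKFB3 passed, higher by 0.40 and 0.38, but not with the processed signals (adjusted p 0.134 and 0.13). The median of that list was 0.0605 to 0.216 on the CCL19 arrays. Ribosomal proteins (0.00347) and motility and actin genes (0.04) were higher once CXCL12 replicate 3 was left out, but no list passed with an estimated correlation and the donor block as well.

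Against untreated cells, several genes of the response to low oxygen were higher in cells that had migrated to CXCL12, with 10 members higher and 1 lower of 32 in the hypoxia and glycolysis list. That list passed camera, but not with an estimated correlation (adjusted p = 0.837) or with median centring (0.332). ANKRD37, a target of the oxygen-regulated factor HIF-1, was higher by 1.20 ± 0.24 (2.29-fold, adjusted p 0.0188). DDIT4, which restrains the growth kinase mTOR under stress, was higher by 1.14 ± 0.27 (2.20-fold, 0.0259), and SLC16A3, the lactate exporter of glycolytic cells, by 1.12 ± 0.28 (2.17-fold, 0.0302), each on 3 of 3 arrays. EGLN1, the oxygen sensor that marks HIF for destruction, the glycolytic enzyme gene ALDOC and the glycolysis regulator PFKFB3 were higher by 0.82 ± 0.14, 0.67 ± 0.09 and 0.67 ± 0.09, all with an adjusted p of 0.0169 and on 3 of 3 arrays. ARPC1B, a subunit of the complex that nucleates branched actin at the leading edge, was higher by 1.17 ± 0.28 (0.0269). SYMPK, the neuronal ASTN2, EDARADD of the ectodysplasin pathway and PLEC, which links cytoskeletal filaments, rose by 1.04 to 1.28. With median centring EGLN1 and ALDOC passed, whereas ANKRD37 (adjusted p 0.109), DDIT4 (0.39), SLC16A3 (0.337), ARPC1B (0.0679), ASTN2 (0.0701), EDARADD (0.325), PLEC (0.0887) and PFKFB3 (0.876) did not. Of the 38 genes named in this text that passed in CXCL12_migrated cells, 26 kept the call with the processed signals, 7 with the value table and 0 without CXCL12_migrated replicate 2 or replicate 3.

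For several of the genes with large changes in CXCL12_migrated cells, a further probe of the gene moved far less or the other way. The coagulation factor gene F7 was lower by −2.31 ± 0.47 (4.97-fold lower, adjusted p 0.0189), but its other probe read 0.01. The G protein gene GNAZ read −2.28 ± 0.55 (0.0274), with −0.16 on its other probe. For the pancreatic factor PAX4 the values were −2.15 and −0.32, for the heat-sensing channel TRPV1 −2.11 and −0.29, for the endothelial gene PLVAP −1.90 and −0.14, and for ASTN2, an increase, 1.24 and −0.28. The keratin KRT25, the taste G protein GNG13 and the neural factor ST18 fell to −1.93 to −1.95 and had no further measured probe. Without background subtraction GNAZ (0.0719), PAX4 (0.0773), TRPV1 (0.0997), KRT25 (0.0767), GNG13 (0.15) and ST18 (0.122) did not pass, and no gene of this paragraph passed without CXCL12_migrated replicate 2 or replicate 3. GP9, a subunit of the platelet receptor for von Willebrand factor, was lower by −0.88 ± 0.16 (0.0169) on 3 of 3 arrays.

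The CXCL12_migrated comparison had 2242 passing genes of 15326, 1060 higher and 1182 lower (47.3% higher). The share higher was 59.1% with the processed signals (975 genes) and 57.6% with the value table (231). The count was 0 without CXCL12_migrated replicate 2 or 3, 2426 without its replicate 1, 1107 within the later extraction day, where 58.9% were higher, and 3782 without CXCL12 replicate 3, which included all 2242. With the donor as a fixed block, for these donors only, it was 3992. Camera placed hypoxia and glycolysis higher (adjusted p 4.61e-06, list median 0.61, adjusted p = 0.837 with an estimated correlation), with 12 members higher and 1 lower adjusted over the list alone. Motility and actin genes were higher (0.017, median 0.26, adjusted p = 1 with an estimated correlation) and platelet markers lower (0.0129, median −0.26, adjusted p = 0.837 with an estimated correlation). Median centring ended these calls (0.332, 0.894 and 0.336); hypoxia and glycolysis kept 0.00598 within the later day, where motility and actin genes had 0.145. Platelet markers had 0.16 without replicate 2. Fry passed hypoxia and glycolysis (0.0413), monocyte markers (0.0246), neutrophil markers (0.0246), B cell markers (0.0451) and platelet markers (0.0451). CXCR4 (0.05 ± 0.77, 0.973), CCR7 (0.08 ± 0.55, 0.939) and ACKR3 (−0.17 ± 0.09, 0.215) did not pass.

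Several genes of oxygen sensing and glycolysis were also higher in cells that had migrated to CCL19, with 11 members higher and 2 lower of 32 in the hypoxia and glycolysis list. That list passed camera, but not with an estimated correlation (adjusted p = 0.973) or with median centring (0.933). ALDOC and PFKFB3 of this list had also passed with CCL19 in plates. PFKFB3 was higher by 0.84 ± 0.09 (adjusted p 0.00744), ALDOC by 0.63 ± 0.09 (0.00747), EGLN1 by 0.86 ± 0.14 (0.00757), P4HA1, a collagen hydroxylase induced by HIF, by 0.56 ± 0.10 (0.00805) and ANKRD37 by 1.20 ± 0.24 (0.0108), each on 3 of 3 arrays. HK2, the first enzyme of glycolysis, was higher by 1.13 ± 0.31 (2.19-fold, 0.0287), although a dimmer probe read −0.14. SYMPK was higher by 1.83 ± 0.32 (3.56-fold, 0.00805). The zinc finger gene ZNF784, the DNA repair gene APTX, the developmental factor FOXD3, the adaptor KCTD17 and the Wnt ligand WNT10A rose by 1.12 to 1.76 on 3 of 3 arrays; the other probes of KCTD17 and WNT10A read 0.43 and 0.07. Median centring left EGLN1 and ALDOC past the threshold but not PFKFB3, which turned to −0.18 (adjusted p 0.565), ANKRD37 (0.165), HK2 (0.152) or P4HA1 (0.0882). Lower were the JNK scaffold SPAG9 (−2.11 ± 0.64, 0.0408), SRD5A3 of protein glycosylation (−2.06 ± 0.65, 0.0459), GNAZ, TRPV1, F7, GNG13, PAX4 and the SUMO ligase PIAS2, between −1.78 and −1.97. The other probes of SPAG9 (0.00), F7 (0.07), TRPV1 (−0.19), GNAZ (−0.22), PAX4 (−0.18) and PIAS2 (−0.07) changed far less. GP9 was lower by −0.77 ± 0.16 (0.0121, 3 of 3 arrays). Without background subtraction HK2 (0.0539) and all of these lower genes but GP9 missed the threshold (0.095 to 0.263). With the processed signals SPAG9 (0.0556), SRD5A3 (0.0594) and PIAS2 (0.0525) did not pass, nor SRD5A3 with extraction day as a block (0.0521). Of the 39 genes named in this text that passed in CCL19_migrated cells, 35 kept the call with the processed signals and 33 with the value table, and none of the genes of this paragraph passed without CCL19_migrated replicate 3 or without donor 2.

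For CCL19_migrated cells 3384 of 15322 genes passed, 1910 higher and 1474 lower (56.4% higher, and 40.7% of 8631 with median centring). With that centring the median of all genes was −0.227, against −0.00929 with loess; for CXCL12 it was −0.122 (−0.0514 with loess), for CCL19 −0.16 (−0.00623) and for CXCL12_migrated −0.121 (0.00933). The count was 0 without CCL19_migrated replicate 3 or without donor 2, 555 without CCL19_migrated replicate 2 (71.7% higher), 2817 without its replicate 1, 1553 without donor 3, 1766 within the later extraction day and 4548 without CXCL12 replicate 3, 3383 of them shared. Hypoxia and glycolysis were higher in camera (adjusted p 7e-05, list median 0.56, adjusted p = 0.973 with an estimated correlation), with 15 members higher and 3 lower adjusted over the list alone. That list had 0.0295 within the later day and 0.933 with median centring, where camera passed 5 other lists. CXCR4 (0.25 ± 0.77, adjusted p 0.853) passed only without CXCL12 replicate 3, at 0.0467, on 3 of 3 arrays. CCR7 (0.33 ± 0.55, 0.717) and ACKR3 (−0.22 ± 0.09, 0.0994) did not pass.

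The probe of WNT5A itself was well above background in Cy3 on 1 of 3 arrays of CXCL12 and of CCL19, on 0 of 3 of each migrated group, and in Cy5 on 1 of 3 in each group. Neither a fold nor a ratio to untreated cells is therefore given for it. A decrease or a small change of WNT5A was not detectable with this probe. A rise to well above background in Cy3 was not seen in the migrated groups, and whether this probe would show one was not tested. FZD5, a receptor of WNT5A, was higher in CXCL12_migrated cells by 0.38 ± 0.10 (0.0359) and in CCL19_migrated cells by 0.48 ± 0.10 (0.0126), on 3 of 3 arrays each, and did not pass for CXCL12 (0.31 ± 0.10, 0.163) or CCL19 (0.25 ± 0.10, 0.164). The processed signals (0.077) and the value table (0.116) ended the call of FZD5 in CXCL12_migrated cells, as did leaving out CXCL12_migrated replicate 2 or replicate 3, and CCL19_migrated replicate 3 (0.0824) or replicate 2 (0.0673) ended the other.

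Frizzled-2, the receptor gene FZD2, had larger changes: 0.85 ± 0.19 (adjusted p 0.115) for CXCL12, 1.10 ± 0.19 (0.0304) for CCL19, 1.08 ± 0.19 (0.0169) for CXCL12_migrated and 1.22 ± 0.19 (0.00749) for CCL19_migrated, positive on all 12 arrays and under each setting run. The CCL19 call of FZD2 did not hold with the value table (0.0821). WNT9A, a ligand, was higher in the last 3 of these groups by 0.58 ± 0.13 (0.0381), 0.72 ± 0.13 (0.0169) and 0.72 (0.00832). AXIN1, a scaffold of beta-catenin destruction, was higher in CCL19 and CXCL12_migrated cells by 0.83 ± 0.20 (0.0464) and 0.89 (0.0222), and WNT4 was lower by −0.42 and −0.41. With the processed signals WNT9A (0.0883), AXIN1 (0.073) and WNT4 (0.251) did not pass for CCL19, nor WNT4 for CXCL12_migrated (0.106). No Wnt gene passed for CCL19 without any one of CCL19 replicate 1, 2 or 3, for CXCL12_migrated without its replicate 2 or 3, or for CCL19_migrated without its replicate 3. ROR2, a co-receptor of WNT5A, was higher in CCL19_migrated cells by 0.41 ± 0.07 (0.00851) and, with median centring, read −0.09 (0.534). Of the 38 measured genes of noncanonical Wnt signalling, 2 were higher and 1 lower with CCL19, 5 and 3 with CXCL12_migrated, and 8 and 3 with CCL19_migrated. Adjusted over the list alone, the pairs were 4 and 4, 6 and 4, and 9 and 3. Among 41 Wnt ligands, receptors and inhibitors, 4 were higher and 2 lower, 4 and 3, and 11 and 4. Neither list passed camera against untreated cells, but with median centring Wnt ligands, receptors and inhibitors were higher for CXCL12 (0.0147) and CCL19_migrated (0.048). With an estimated correlation that list had 0.967 and 0.973.

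Whether migration itself went with a change is asked by the migrated against the plate-treated arrays, 6 against 6. A dye effect cancels here only if it is equally large on both kinds of array. In the pairs without CXCL12 replicate 3, log ratios of genes outside the hypoxia and glycolysis list were wider on the migrated array. Their SD was 1.13 to 1.46 times that of the paired plate-treated array. The 3 genes nearest to passing in the positive direction all belong to the response to low oxygen: BNIP3, which directs mitochondria to degradation (0.65 ± 0.10), ZNF395, a HIF-induced factor (0.65 ± 0.13; other probe 0.09), and PFKFB3 (0.43 ± 0.09). ANKRD37 (1.05 ± 0.24) and EGLN1 (0.61 ± 0.14) followed, and lower were TRIM10 of red cell development (−0.95 ± 0.15; other probes −0.14 and 0.01), the growth factor adaptor FRS3 (−0.83 ± 0.14), the matrix gene TNR (−0.81 ± 0.14) and GP9 (−0.86 ± 0.16), all with an adjusted p of 0.642. LEF1, a transcription factor of naive T cells and the Wnt pathway, was 1.41 ± 0.48 (adjusted p 0.711) and 0.92 without CXCL12 replicate 3. In limma 0 of 15308 genes passed, with 946 at an unadjusted p under 0.05, 1 with quantile scaling and 0 with the donor block. Without CXCL12 replicate 3 the counts were 0 (760 unadjusted) and, with the donor block, 93 (6 higher, 87 lower); BNIP3 then passed (0.57 ± 0.09, adjusted p 0.039), as did ZNF395 and PFKFB3 (0.0475), TRIM10 and FRS3 (0.0407), TNR (0.0384), GP9 (0.0341) and LEF1 (0.81 ± 0.14, 0.0439).

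Hypoxia and glycolysis was the list with the lowest adjusted p in that comparison, 1.8e-11 in camera, with a median of 0.51 and 29 of 32 members positive; with an estimated correlation, adjusted p = 0.556. Over all genes 0 members passed, and 14 were higher and 0 lower adjusted over the list alone. The list had 5.79e-14, a median of 0.33 and 16 members higher adjusted over the list alone without CXCL12 replicate 3. It had 3.86e-05 within the later extraction day and with median centring 3.57e-05, and fry gave 0.213. An exact permutation of the arrays within donors, two-sided and added after the data were seen, gave p = 0.00926 for the median of the list over all arrays, the smallest p these permutations can give, which is 0.259 adjusted over the 28 lists. The permutation p was 0.037, or 0.519 adjusted, without CXCL12 replicate 3.

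Platelet markers were lower in migrated cells (camera adjusted p 0.000604, median −0.21, 0.00788 without CXCL12 replicate 3), with 0.158 under median centring and 0.197 without replicate 2; with an estimated correlation, adjusted p = 0.556. B cell markers (0.0374, lower) passed in neither the donor-blocked fit (0.0575) nor without CXCL12 replicate 3 (0.227), and had 0.556 with an estimated correlation. Ribosomal proteins (0.00014), the respiratory chain (0.00805), motility and actin genes (0.0112) and naive T cell genes (0.0124) were higher over all arrays, with an adjusted p = 0.918 for each with an estimated correlation. Leaving out CXCL12 replicate 3, they had 0.835, 0.904, 0.215 and 0.051, while heat shock (0.0251), memory and effector T cell genes (0.0251) and NK cell markers (0.00355) were lower. With the donor block and an estimated correlation, no list passed without that array.

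**Figure D1:**
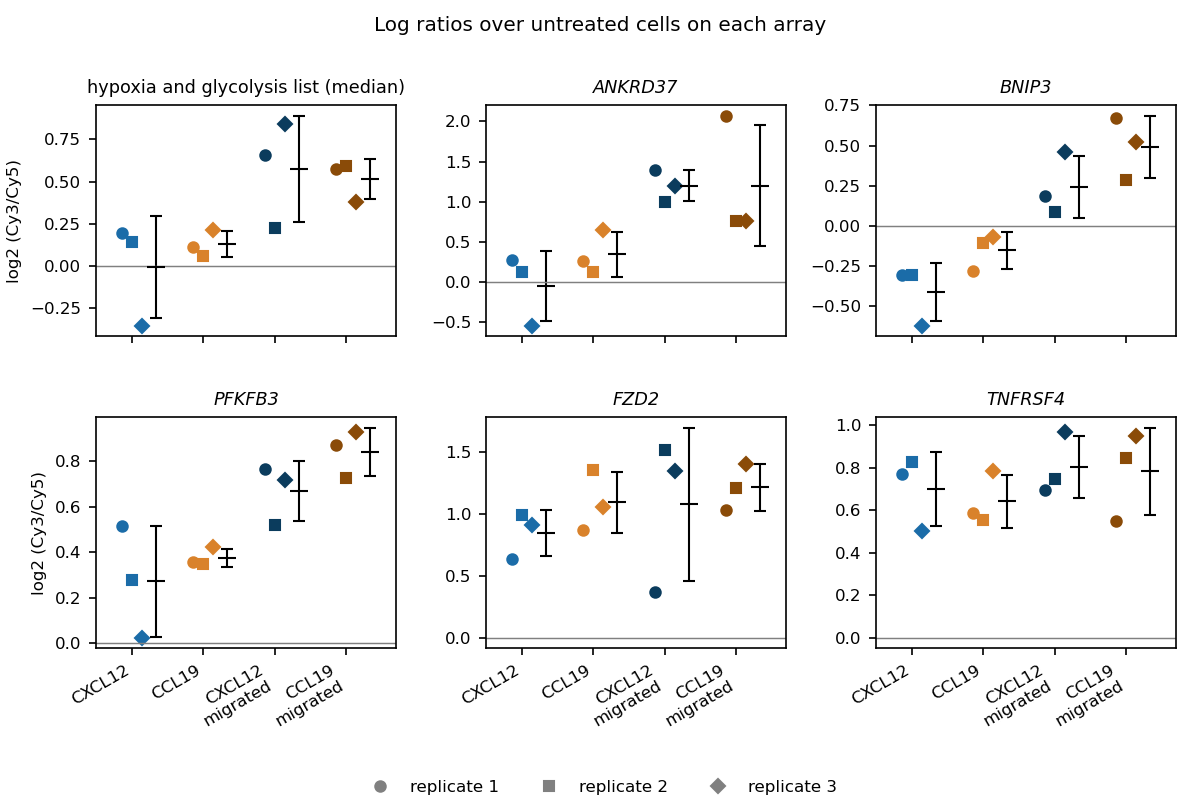
Log2 ratio of Cy3 (chemokine) over Cy5 (untreated) on each array (vertical axis) for the median of the hypoxia and glycolysis list and for ANKRD37, BNIP3, PFKFB3, FZD2 and TNFRSF4, by group; symbols mark replicates, and black bars give the mean and SD of 3 arrays. The mean of BNIP3 was −0.41 in CXCL12, −0.15 in CCL19, 0.24 in CXCL12_migrated and 0.49 in CCL19_migrated cells.

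Within each chemokine, the migrated arrays were compared with those from plates. BNIP3 was the gene with the smallest p in the positive direction for both, at 0.66 ± 0.15 for CXCL12 (adjusted p 0.555) and 0.65 ± 0.15 for CCL19 (adjusted p 1). For CXCL12, ZNF395 (0.75 ± 0.18) and ANKRD37 (1.25 ± 0.34) followed, and CARMIL1, a regulator of actin capping (−2.17 ± 0.39, −1.63 without CXCL12 replicate 3), and the developmental factor NODAL (−1.93 ± 0.28, −1.63 without it) were lower, all at 0.555, as was ADAMTS8, whose probe was not well above background on every array. For CCL19, the neuronal gene NRSN1 (0.43; other probe −0.23), the cartilage gene MATN3 (0.55), ASB8 of protein ubiquitination (−0.54; other probe 0.03), TRIM10 (−0.95 ± 0.22) and C12orf42, lower with a probe not well above background on every array (other probe 0.13), followed at 1. In limma 0 of 15324 and 0 of 15316 genes passed, with 964 and 269 at an unadjusted p under 0.05; without CXCL12 replicate 2, 1 gene passed for CXCL12, and without CXCL12 replicate 3 and with the donor block, 2 were lower for CCL19. CXCR4 differed by 1.81 ± 1.10 for CXCL12, or 0.05 without CXCL12 replicate 3, and by 0.12 for CCL19, and CCR7 by 1.45, or 0.23 without that array, and 0.30.

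Hypoxia and glycolysis genes were higher in migrated cells for each chemokine in camera, at 4.02e-08 for CXCL12 (median 0.63, and 1.88e-09 with a median of 0.32 without CXCL12 replicate 3) and 1.12e-09 for CCL19 (median 0.44); with an estimated correlation, adjusted p = 0.652 and 0.821. Within the later day they had 0.000254 and 0.00154. Platelet markers were lower for CXCL12 (0.00363, median −0.24, 0.0183 without CXCL12 replicate 3, 0.153 without replicate 2) and for CCL19 (0.0148, median −0.17, 0.0788 with the processed signals, 0.817 without replicate 2); with an estimated correlation, adjusted p = 0.652 to 0.701 for all lists of CXCL12 and 0.821 for those of CCL19. Neutrophil markers were lower for CXCL12 (0.00872, 0.0481 without CXCL12 replicate 3, 0.0925 without replicate 1) and naive T cell genes higher (0.000678, median 0.75, 0.00781 without CXCL12 replicate 3). Ribosomal proteins (8.75e-08, median 1.58), the respiratory chain (1.14e-06, median 0.75), motility (0.000333), the T cell receptor complex (0.0136) and homing (0.0331) were higher for CXCL12 with its replicate 3, and had 0.888, 0.156, 0.151, 0.393 and 0.408 without it; homing had 0.0912 with the donor block. Without it, immediate-early genes (9.8e-05), NK cell markers (7.17e-05), heat shock (0.00949) and memory genes (0.0122) were lower, and none passed with the donor block and an estimated correlation. For CCL19, Wnt ligands, receptors and inhibitors were higher (0.0299, median 0.10), with 0.118 for the processed signals, 0.0634 without CXCL12 replicate 3 and 0.973 without replicate 3.

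**Figure D2:**
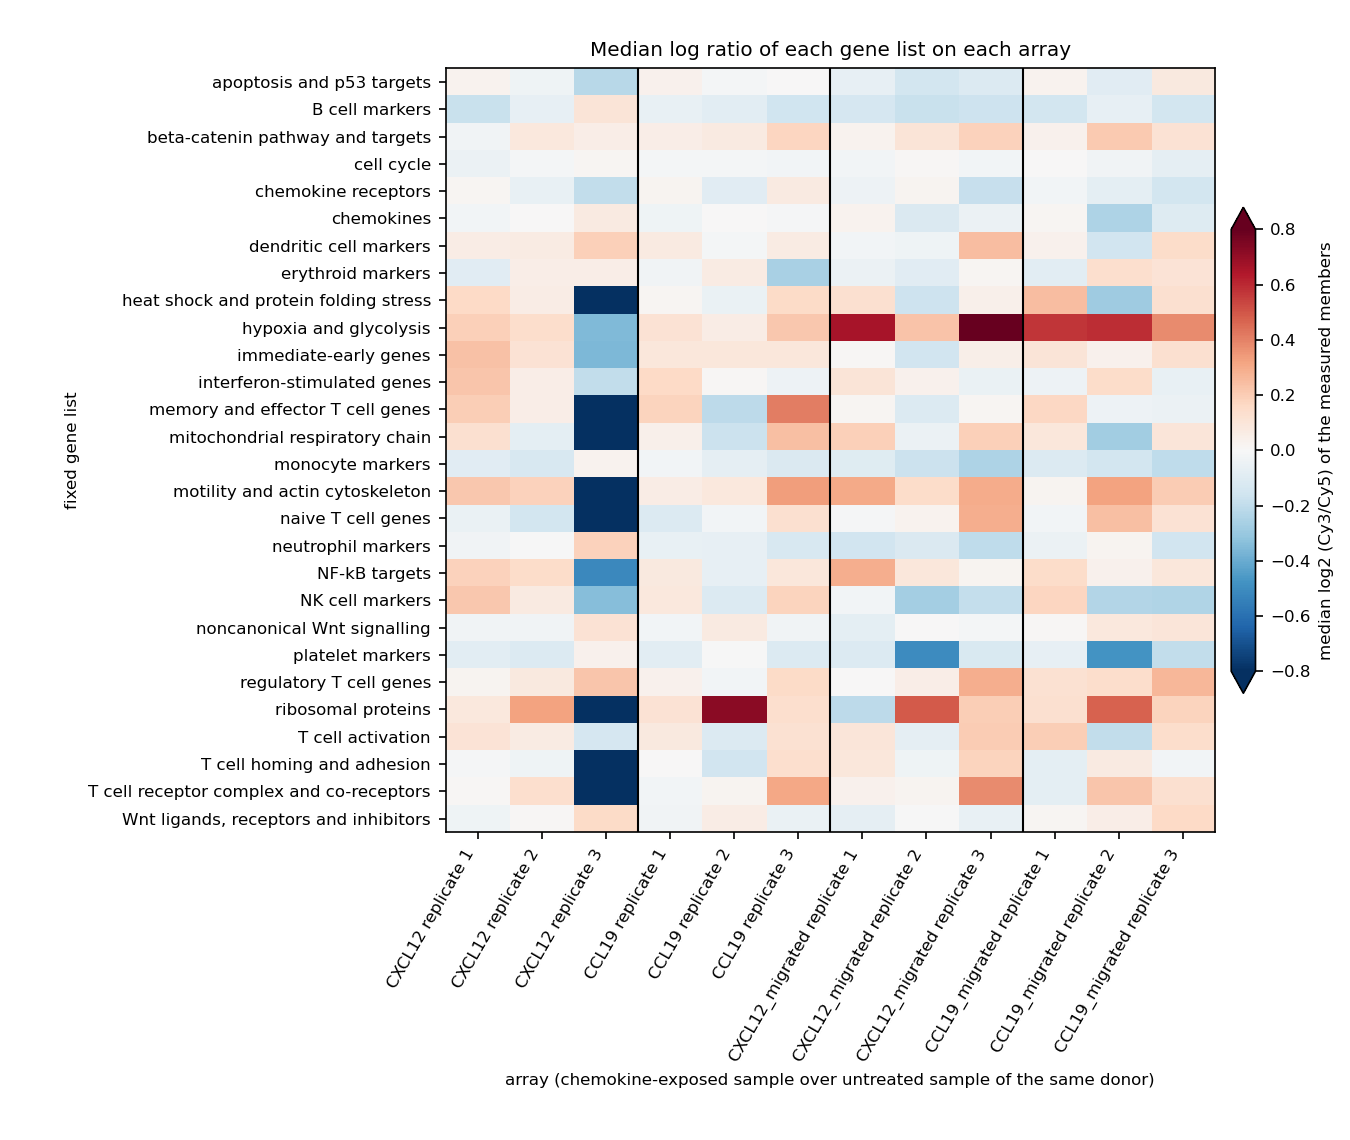
Median log2 ratio of Cy3 over Cy5 of the measured members of each of the 28 gene lists (one line each) on each of the 12 arrays (columns, by group and replicate), from blue (lower than untreated) to red (higher), with colours saturated at the ends of the scale. Ribosomal proteins had −4.55 on CXCL12 replicate 3 and −0.207 to 0.722 on the other arrays.

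The chemokines were compared with each other in plates and after migration. In plates, the zinc finger gene ZNF136 (0.74 ± 0.19; other probe −0.07) and VPS37B of the endosomal sorting machinery (1.39 ± 0.38) were nearest to passing toward CXCL12, with ADAMTS8, a protease gene not well above background on every array. Toward CCL19 were the cyclin CCND3 (−0.43 ± 0.13; other probe 0.01), PRR5 of the mTOR complex (−0.52 ± 0.16; other probe −0.13) and the deacetylase HDAC7 (−0.54 ± 0.18; other probe −0.25), all with an adjusted p of 0.964. After migration, ASB8 (0.49 ± 0.11; other probe 0.00) and the adhesion gene CDH1 (0.50 ± 0.14) leaned toward CXCL12, and the kinase PAK3 (−0.50 ± 0.12; Cy5 well above background on 4 of 6 arrays), BARX2 (−0.48 ± 0.12) and ROR2 (−0.44 ± 0.11) toward CCL19, all at an adjusted p of 1. ALKBH3, a repair enzyme, was well above background in Cy3 on 3 of 3 CXCL12_migrated and 0 of 3 CCL19_migrated arrays. Its mean Cy3 intensity was 1.42-fold higher in the former, which is a plain ratio and no lower bound, and it did not pass in limma (adjusted p 1). In limma 0 of 15319 genes passed in plates and 0 of 15316 after migration, with 134 and 199 at an unadjusted p under 0.05; 1 gene passed in plates without CXCL12 replicate 2. CXCR4 differed by −1.89 ± 1.10 in plates, −0.13 without CXCL12 replicate 3, and by −0.20 after migration, and CCR7 by −1.41, −0.18 without that array, and −0.25.

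In plates camera placed 8 lists lower with CXCL12 than with CCL19, led by ribosomal proteins (adjusted p 2.77e-14, median −1.67), the respiratory chain (7.5e-09), naive T cell genes (6.5e-05) and memory genes (6.5e-05), and followed by motility (0.000297), the T cell receptor complex (0.00271), heat shock (0.00611) and homing (0.00665). With an estimated correlation, adjusted p = 0.611 for each, and without CXCL12 replicate 3 none passed (0.178 to 0.961), while immediate-early genes were higher with CXCL12 (0.0242), though no list passed once the donor block and an estimated correlation were used there. With the donor as a block, dendritic cell markers were higher with CXCL12 (0.0361, against 0.124, and 0.611 with an estimated correlation). After migration, Wnt ligands, receptors and inhibitors were lower with CXCL12 than with CCL19 (0.011, median −0.10), as were noncanonical Wnt genes (0.0335, median −0.07), neutrophil markers (0.0335), immediate-early genes (0.0335, median −0.11) and erythroid markers (0.0379), while the respiratory chain was higher (0.0335, median 0.13). With an estimated correlation, adjusted p = 0.683 to 0.978 for these 6. Only Wnt ligands, receptors and inhibitors passed both with the processed signals and with median centring, and that list had 0.0711 without replicate 1. Erythroid markers (0.0596), immediate-early genes (0.0752) and the respiratory chain (0.0542) did not pass with the donor block.

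The last comparison asks whether migration changed gene expression differently for the chemokines, as the difference of the CXCL12 and CCL19 migration effects. ASB8 (0.53 ± 0.16; other probe −0.01), ZNF205 (0.61 ± 0.19) and GTF2H5, a subunit of a transcription factor (0.60 ± 0.19), and in the other direction PAK3 (−0.73 ± 0.16), BARX2 (−0.64 ± 0.16) and ADAMTS8, not well above background on every array, were nearest to passing, all with an adjusted p of 0.981. In limma 0 of 15308 genes passed, with 177 at an unadjusted p under 0.05, 0 with the donor block and 0 without CXCL12 replicate 3. Camera passed 10 lists, each with an adjusted p = 0.719 with an estimated correlation.

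**Figure D3:**
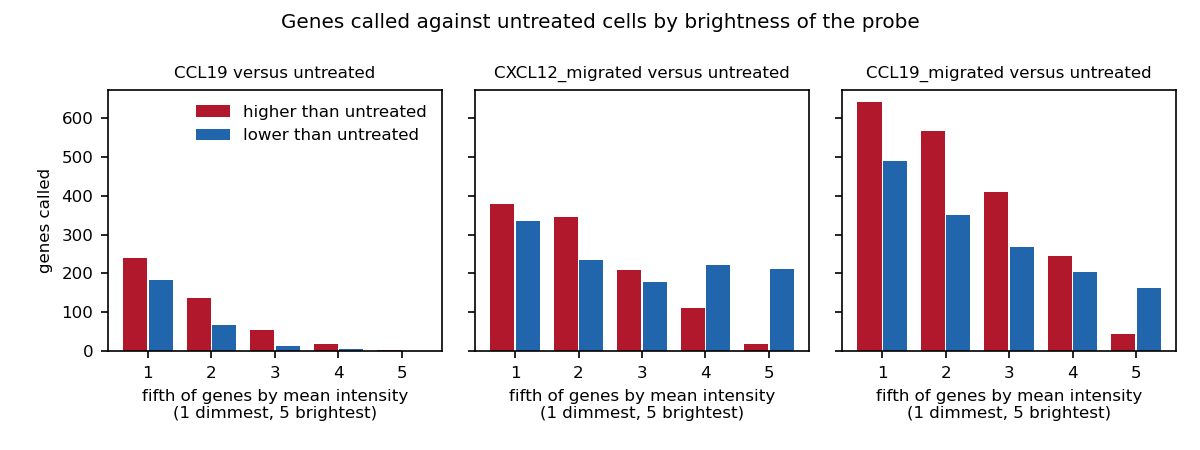
Number of genes (vertical axis) higher or lower than untreated cells, in 5 equal classes of genes from the dimmest (1) to the brightest (5) mean intensity, for CCL19, CXCL12_migrated and CCL19_migrated cells. For CCL19, 422 passing genes were in the dimmest class and 3 in the brightest. For CCL19_migrated the counts were 1130 and 208. The fit included CXCL12 replicate 3, whose low values for bright genes can widen their spread in every group.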

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

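Chosen only after the result was seen were the settings without CXCL12 replicate 3, the comparison of probes of one gene, the tests of other cells, of a CXCL12 effect, of a dimmer target and of wider log ratios, the splits within donors and the permutation of arrays within donors. The test of the difference between the CXCL12 and CCL19 migration effects gave 10 gene lists whose change with migration differed between the chemokines, all by camera. Naive T cell genes had a more positive migration effect for CXCL12 (adjusted p 0.000637, median 0.75), though none of these genes passed alone and the change of the list median was the larger for CCL19 in donors 1 and 2, and they had 0.719 with an estimated correlation; without CXCL12 replicate 3 they had 0.0383 (median 0.11), and 0.234 with the donor block as well. The mitochondrial respiratory chain differed the same way (1.76e-08, median 0.90, and 0.00111 with a median of 0.17 without that array, 0.719 with an estimated correlation). Neutrophil markers differed the other way (0.0057, median −0.14, and 0.0383 with a median of −0.11, 0.719 with an estimated correlation). Wnt ligands, receptors and inhibitors (0.00314, median −0.14) and noncanonical Wnt signalling (0.013, median −0.09) were lower for CXCL12, with 0.0939 and 0.202 without the array.

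The other lists of that test were ribosomal proteins (2.29e-07, median 1.44), motility and actin (0.000591, 0.57), the T cell receptor complex (0.00225, 0.70), T cell homing (0.013, 0.75) and memory and effector T cell genes (0.021, 0.28), all more positive for CXCL12. Their adjusted p-values were 0.953, 0.562, 0.193, 0.645 and 0.333 without CXCL12 replicate 3, where immediate-early genes (7.02e-06), NK cell markers (0.00872) and erythroid markers (0.0383) were lower for CXCL12, with no list passing there with the donor block and an estimated correlation. Each of the 10 lists had an adjusted p = 0.719 with an estimated correlation. With the donor block memory genes had 0.0549, and without CXCL12 replicate 3 and with the donor block the respiratory chain had 0.0603 and neutrophil markers 0.0626. Of 100 splits of the arrays, the real one included, 33 gave as many lists, with 10 in the real split and 16 in the highest other, so chance is not excluded; within donors 57 of 100 did, with 14 in the highest other. For genes, all 100 splits gave 0 either way, as the real one did.

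CXCL12 replicate 3 lay behind most of these lists: its Cy3 signal was low for abundant messengers, with 702 genes below −2. Cells of another human type in the sample would still carry ribosomal messengers, but the median of the ribosomal protein list was −4.55 on this array and −0.207 to 0.722 on the others, which argues against them. An effect of CXCL12 would be shared by the other CXCL12 arrays, where those 702 genes had a median of 0.03 (0.0296), and this argues against it. Loss of labelled target, through poor labelling or degraded RNA, remains open: the slope of log2 Cy3 on log2 Cy5 over genes was 0.713 here and 0.888 to 0.994 elsewhere. The Cy3 channel was not dim as a whole. In it 92.7% of features were well above background, against 84.2% to 89.3% on the other arrays of donor 3. No array repeats this sample to separate the steps, so whether a step failed, and which, cannot be told.

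Of the passing genes against untreated cells, 59.0% were among the dimmest 20% of genes for CCL19, 31.8% for CXCL12_migrated and 33.4% for CCL19_migrated. These shares come from the fit with CXCL12 replicate 3, whose low signal for abundant messengers can widen the spread of bright genes in every group. If most passing genes reflected a change of the messenger, other passing probes of the same genes would go the same way. In CCL19_migrated cells 51.5% of 239 did, close to an even division of signs, with 55.6% of 124 for CXCL12_migrated and 50% of 10 for CCL19. That argues against a change of the messenger as the common source of both calls for most of these genes. It is what an effect tied to the probe, such as dye bias without a swap, predicts. The other probe was always dimmer than the one that stood for the gene, so its sign cannot show whether the brightest probe's call was real. In the order CCL19, CXCL12_migrated, CCL19_migrated, bright other probes, passing or not, went the same way in 50% of 2, 65.8% of 73 and 57.1% of 91 on all arrays. Without CXCL12 replicate 3 passing other probes did in 56.4%, 60.8% and 54.5%. Bright other probes, passing or not, did there in 80.8% of 26, 72.9% of 240 and 68.4% of 206. A change of the messenger thus stays open for part of the calls of genes with a bright other probe. A real difference between chemokine-exposed and untreated cells stays open for single genes such as FZD2, whose value rests on 1 probe.

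Hypoxia and glycolysis genes were higher in migrated than in plate-treated cells by camera but not with an estimated correlation (adjusted p 0.556), and the median difference within pairs was uneven, from 0.0274 with 19 of 32 members higher (CXCL12 replicate 2) and 0.143 (CCL19 replicate 3) to 1.09 (CXCL12 replicate 3). A dimmer Cy3 target in the migrated arrays stays open, since the migrated array was the brighter one in Cy3 in 1 of 5 pairs only, where the difference was 0.508. In these 5 pairs the difference did not grow with dimming but fell at each step from the brightest to the dimmest migrated array. The cause of this dependence on Cy3 brightness was not tested. The list difference was 0.467 at nearly equal brightness (log2 difference −0.0142, CCL19 replicate 2) and 0.375 at −0.2 (CCL19 replicate 1). Where the migrated array was dimmest (−0.27 and −0.251) it was 0.0274 and 0.143. Wider log ratios of all genes stay open too: with the plate-treated ratios widened by the ratio of SDs, the mean over 5 pairs was 0.266 (SD 0.228, lowest −0.0145), against 0.304 before. Of 108 assignments within donors without CXCL12 replicate 3, 4 gave a median as large, the real one included, with 0.36 in the real one and 0.438 in the highest other. The permutation p was 0.037 for this list, which was singled out in these same data, and 0.519 adjusted over 28 lists, so chance is not excluded. Migration, a selection of cells that were already more glycolytic, and a lower oxygen level where migrated cells collected also remain open, and none of these 3 was tested.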

How the results depend on the processing

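Chosen only after the result was seen were the settings without CXCL12 replicate 3 for all comparisons, alone or with a block, and the day block for lists. Passing genes against untreated cells are given in the order CXCL12, CCL19, CXCL12_migrated, CCL19_migrated, from 0, 715, 2242 and 3384. CCL19_migrated kept within 1.5 times of its count with the processed signals (2352), quantile scaling (2848) and the donor block (4698). Among named genes with a call, 3 values reversed, all with median centring: PFKFB3 for CCL19 (−0.282) and for CCL19_migrated (−0.175) and ROR2 for CCL19_migrated (−0.0877). In 4785 cases a named gene kept its call and direction, or stayed without a call and moved by less than the standard error. In 545 cases a gene without a call moved further, in 662 a call was lost and in 115 one was gained. A change of sign was not counted for genes without a call. List calls held in 313 cases, weakened in 293 and reversed in 70.

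With the Agilent processed signals the first 3 counts were 28, 167 and 975. Median centring gave 2827, 3837 and 8631 for the last 3. Quantile scaling gave 1256 for CXCL12 and 2773 for CCL19, and 1 gene for migrated against plate-treated cells. For CCL19, no background subtraction gave 1810 and the stricter filter 236. All probes as separate features gave 3640, 7879 and 11124 for the last 3, where more features were tested. The replicate block gave 982, 2261 and 3992 for the first 3, and ended 1 call of a named gene, ARPC1B for CCL19_migrated (0.0611, against 0.0468). It added 16 calls of named genes for CXCL12 and 3 for CCL19, and changed no call of a list other than those given with the results. Only the arrays compared gave 938 and 1571 for the migrated groups, with fewer arrays to estimate the spread. Extraction day as a block gave 200 and 1258 for CXCL12 and CCL19. The deposited value table gave 26, 231 and 2004 for the last 3. It gave no test of PLEC for CXCL12_migrated. Without CXCL12 replicate 3 and with the replicate block the 4 counts were 3142, 5226, 7386 and 7731, with 2 for CCL19_migrated against CCL19 and 93 for migrated against plate-treated cells, or 214 with 1 mean for each of these 2 kinds of array. Apart from the settings that tested more features or used fewer arrays, the cause was not tested.

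Leaving out 1 array or donor gave 0 to 1 gene for CXCL12, 0 to 1175 for CCL19, 0 to 3782 for CXCL12_migrated and 0 to 4548 for CCL19_migrated, with fewer arrays as the design of the setting. It gave 0 to 1 for CXCL12 against CCL19 and for CXCL12_migrated against CXCL12. The comparison of the migrated groups and the difference of the migration effects gave 0 genes in every setting run.

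Of the 280 list tests, camera passed 52, and 44 to 54 under the scaling, block and leave-out settings. With an estimated correlation 0 passed, and 0 with the replicate block and without CXCL12 replicate 3; fry passed 5, and 30 with that block and without that array. The cause was not tested.

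Lists that changed direction did so mainly when CXCL12 replicate 3 was left out. With the replicate block and without that array, adjusted p-values from camera, camera with an estimated correlation and fry, where the sign differed, were as follows. For CXCL12 against CCL19 they were 0.612, 0.805 and 0.858 for homing, 0.391, 0.805 and 0.858 for the T cell receptor complex, 0.0112, 0.64 and 0.858 for heat shock, 0.088, 0.796 and 0.858 for memory genes, 0.0183, 0.64 and 0.858 for the respiratory chain, and 0.00211, 0.64 and 0.858 for motility. For CXCL12 against untreated cells they were 0.0758, 0.698 and 0.212 for memory genes, 0.0331, 0.698 and 0.132 for the respiratory chain, and 0.0331, 0.698 and 0.21 for ribosomal proteins. For the difference of the migration effects they were 0.972 and 0.982 (without fry) for homing, 0.0603, 0.664 and 0.813 for memory genes, 0.793, 0.966 and 0.982 for motility, and 0.571, 0.898 and 0.965 for ribosomal proteins. The respiratory chain had 0.223, 0.683 and 0.507 for migrated against plate-treated cells, and 0.961 with fry alone for CXCL12_migrated against CXCL12. Immediate-early genes of the migrated groups reversed with median centring (0.962).

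Over settings without 1 array or donor, reversed lists ranged as follows. For CXCL12 against CCL19 adjusted p was 0.000788 to 0.943 for homing, 6.7e-05 to 0.961 for the T cell receptor complex, 4.73e-05 to 0.178 for heat shock, 8.52e-07 to 0.924 for memory genes, 3.49e-11 to 0.943 for the respiratory chain and 1.01e-05 to 0.349 for motility. For the difference of the migration effects it was 0.000421 to 0.645 for homing, 2.67e-06 to 0.404 for the T cell receptor complex, 5.61e-05 to 0.333 for memory genes, 1.79e-07 to 0.562 for motility and 1.13e-07 to 0.953 for ribosomal proteins. For CXCL12_migrated against CXCL12 it was 0.000148 to 0.946 for the T cell receptor complex and 2.17e-10 to 0.888 for ribosomal proteins. For CXCL12 against untreated cells it was 0.000902 to 0.149 for memory genes, 2.44e-06 to 0.318 for the respiratory chain and 2.09e-11 to 0.0302 for ribosomal proteins. For migrated against plate-treated cells it was 1.61e-06 to 0.904 for the respiratory chain and 2.9e-08 to 0.835 for ribosomal proteins. The cause was not tested. Signal over background limits dim probes: WNT5A was not well above background on every array.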

Other observations

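Chosen only after the result was seen were the setting without CXCL12 replicate 3, with a block and 1 mean for each kind of array, and the splits of all arrays within donors. TNFRSF4 was higher by 0.64 ± 0.10 with CCL19 (adjusted p 0.03), 0.80 ± 0.10 in CXCL12_migrated cells (0.0167) and 0.78 in CCL19_migrated cells (0.00744), on 3 of 3 arrays each, and TNFRSF18, also a co-stimulatory receptor of the tumour necrosis factor family, by 0.59 (0.0237) and 0.71 (0.00946) in the migrated groups, where TNFRSF18 did not pass with median centring (0.0679 and 0.256). TNFRSF9, another receptor of that family, was lower in CXCL12_migrated cells (−0.61, 0.0242). The T cell activation list had 2 members higher and 0 lower of 29 with CCL19, 2 and 3 with CXCL12_migrated and 4 and 5 with CCL19_migrated. CCR4, a receptor for skin and lung homing, was higher by 0.43 ± 0.10 (0.0449), 0.51 (0.0183) and 0.53 (0.00925) in these groups, on 3 of 3 arrays each, while its ligand gene CCL17 was lower by −0.46 (0.0334) with CCL19. Of these, TNFRSF4 (0.0501), CCR4 (0.116) and CCL17 (0.375) did not pass for CCL19 with the processed signals, nor did TNFRSF18 for CXCL12_migrated (0.0503), and CCL17 did not with median centring (0.548). CXCL11, a ligand of CXCR3 and ACKR3, was higher by 0.50 (0.0371), 0.50 (0.0212) and 0.64 (0.00768), and CCL5 by 0.63 ± 0.16 with CCL19 (0.0495; 0.799 with median centring). With the processed signals CXCL11 did not pass for CCL19 (0.127) or CXCL12_migrated (0.0573), nor CCL5 for CCL19 (0.102). No call here held without any one of CCL19 replicate 1, 2 or 3 for CCL19, without CXCL12_migrated replicate 2 or 3, or without CCL19_migrated replicate 3. Of 31 chemokines, 2 were higher and 5 lower in CCL19_migrated cells, and of 21 chemokine receptors 2 were higher and 0 lower.

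Interferon-stimulated genes as a list did not pass camera against untreated cells (adjusted p 0.775 with CCL19, 0.524 in CXCL12_migrated and 0.87 in CCL19_migrated cells). The members that passed there were higher: IFIT3 by 0.48 ± 0.08 with CCL19 (adjusted p 0.0304), 0.57 in CXCL12_migrated (0.0169) and 0.52 in CCL19_migrated cells (0.00749), HERC5 by 0.59 (0.0363), 0.62 (0.0193) and 0.69 (0.00912), and OAS3 by 0.72 (0.0446) and 0.89 (0.0172) in the migrated groups, with 5 of 30 higher in CCL19_migrated cells. CFLAR, an inhibitor of caspase-8 and target of NF-kB, was higher by 0.79 ± 0.14 (0.0304), 0.85 (0.0169) and 0.77 (0.00894), one of 3 NF-kB targets higher and 1 lower of 25 in CCL19_migrated cells. DDIT3, a stress factor, was lower by −1.03 ± 0.20 (0.0181) and −0.96 (0.0119) in the migrated groups, where 2 of 25 heat shock genes were lower after migration to CCL19. Without background subtraction DDIT3 read −0.346 in CCL19_migrated cells and did not pass (0.0585). The B cell surface gene MS4A1 was lower by −0.91 ± 0.23 (0.0313) and −0.98 ± 0.23 (0.0172) in the migrated groups, but without background subtraction by −0.325 (0.0757) and −0.288 (0.105). Lower as well was CSF3R, a receptor gene of myeloid cells that is in the monocyte and neutrophil lists, by −0.58 (0.0169) and −0.34 (0.0182). Of 24 monocyte markers, 1 was higher and 5 lower in CCL19_migrated cells, and of 18 neutrophil markers 1 and 3. With the processed signals HERC5 (0.125) and CFLAR (0.0761) did not pass for CCL19, nor did OAS3 (0.091) and HERC5 (0.0504) for CXCL12_migrated or CSF3R (0.059) for CCL19_migrated. None of these gene calls held without any one of CCL19 replicate 1, 2 or 3 for CCL19, without CXCL12_migrated replicate 2 or 3, or without CCL19_migrated replicate 3.

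In CCL19_migrated cells the remaining lists had 4 higher and 0 lower of 27 apoptosis and p53 genes, 2 and 0 of 21 beta-catenin genes, 3 and 5 of 32 cell cycle genes, 3 and 1 of 10 regulatory T cell genes, 1 and 0 of 19 NK cell markers, 1 and 1 of 18 dendritic cell markers, and 0 of 16 erythroid markers, 0 of 19 naive T cell genes and 0 of 40 ribosomal proteins. Naive T cell genes and ribosomal proteins had list medians of −1.95 and −4.55 on CXCL12 replicate 3, which widens their spread in this fit. None of the interferon-stimulated, apoptosis, beta-catenin, cell cycle, chemokine, chemokine receptor, regulatory T cell or T cell activation lists passed camera in any of the 10 comparisons with all arrays.

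Other splits of the arrays were tried for each count. Where the real count is 0, every split gives as many, so such a result tests nothing. Against untreated cells a split was a reversal of the sign of all log ratios on 1 of the 3 arrays. With the real signs this makes 4 splits, too few for a share under 0.05. A dye effect shared by the arrays would be broken up by a reversal too, so these splits cannot tell it from an effect of the chemokine. For genes, 4 of 4 gave as many for CXCL12 (0 real, 0 in the highest other), 1 of 4 for CCL19 (715 and 0), 1 of 4 for CXCL12_migrated (2242 and 0) and 1 of 4 for CCL19_migrated (3384 and 0). For lists, the numbers were 4 of 4 (5 and 18), 4 of 4 (0 and 2), 2 of 4 (3 and 3) and 4 of 4 (1 and 4). Between groups of 3 arrays there are 10 splits, also too few. For genes, 10 of 10 gave as many in each of these 4 comparisons (0 and 0). For lists, 9 of 10 gave as many for CXCL12 against CCL19 (8 and 15), 2 of 10 for the migrated groups (6 and 7), 8 of 10 for CXCL12_migrated against CXCL12 (9 and 15) and 5 of 10 for CCL19_migrated against CCL19 (3 and 5).

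For migrated against plate-treated cells, all 100 splits drawn gave at least the real count of 0 genes, as they must. The highest other gave 148, and the cause of that was not tested. For lists, 60 of 100 gave as many (7 real, 14 in the highest other), and within donors 74 of 100 did (13 in the highest other), so chance is not excluded; for genes all 100 splits within donors gave 0. Without CXCL12 replicate 3, with the donor block and 1 mean for migrated and 1 for plate-treated arrays, 214 genes passed, 17 higher and 197 lower. Of 100 splits within donors, only the real one gave as many, with 39 in the highest other. That setting was chosen after the result was seen, so this does not exclude chance over the settings tried. The 17 higher genes were GPI, OXSR1, BNIP3, LDHA, MIF, PFKP, RBPJ, ZNF395, ANKRD37, PFKFB3, PDK1, DAPK1, S100A10, EGLN1, HK2, EEIG1 and MRPS6. Lower were GP9, by −0.88 ± 0.11 (adjusted p 0.009), EPAS1, a subunit of the oxygen-regulated HIF (adjusted p 0.009), and the interferon-stimulated genes IFI6 (0.0446) and IFIT2 (0.0473), among others.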
